A study of Mus musculus with 6 samples.

How the data were processed

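RNA was measured on 6 single-colour oligonucleotide arrays, each hybridised with biotin-labelled cDNA made from total RNA of cultured mouse prostate cancer stem-like cells, per the labels' protocols. Cells had been grown without serum in medium with EGF and FGF2, and cDNA had been fragmented and end-labelled with a whole-transcript kit, per the labels' protocols. The deposited table holds log2 expression values, which the authors made with RMA, per the submitters' processing notes. RMA corrects background, brings all arrays to a shared distribution and summarises the probes of each row on a log2 scale, and it narrows differences near background. The version of RMA and the software that ran it are not given in the sources used here.

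The table has 10361 rows and no missing value, with values from 2.87 to 14.1. It holds part of the array, and the rule that selected its rows is not given in the sources used here. The row that varied least had a range of 0.22 over the 6 arrays, and the median range was 1.47, so adjusted p-values and gene list tests refer to these rows and not to the whole transcriptome. No detection call or background level comes with the values, so a low value cannot be called absent and a fold difference from a low value is not a ratio to a true zero. The number of arrays limits the precision. The array's annotation gave 1 gene symbol for 9496 rows, several for 374 and none for 491. Of the rows with 1 symbol, 9486 matched an Entrez identifier of the RefSeq gene table (assembly GRCm38.p6), and no symbol changed in that match. The table's rows cover 9179 of 21900 protein-coding genes of that table. Genes without a row of their own are not analysed here, among them many epithelial and neuroendocrine marker genes. The sources name no genome build for the array, so no coordinates are given.

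Groups were taken from the sample titles and the cell type labels. The free-text description names intraepithelial neoplasia for all 6 samples, including the 3 that the titles and cell type labels give as neuroendocrine. Replicates were numbered in the order of the series, and these numbers do not pair samples. Each title carries a code of its own whose meaning is not given, so dates or batches cannot be compared between the groups. Nothing in the labels says whether the 3 samples of a group came from separate mice or separate cultures. The p-values therefore measure the spread between these samples, which may be partly technical. No 2 arrays held duplicate data: identical values made up at most 0.106% of rows in any pair.

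One value per gene was kept, from rows with 1 symbol, and the row with the highest mean for the 6 genes with more than 1 row, which left 9490 genes. The groups were compared with limma 3.58.1 in R 4.3.3 on the log2 values as deposited, with a mean per group, the contrast TNE minus TPIN, empirical Bayes moderation and a two-sided test. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. Differences are given as log2 differences, TNE minus TPIN, with the moderated standard error (SE), or as the fold on the RMA scale.

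Gene lists were fixed before the data were examined: 32 lists with 811 entries, of which 529 had a row. The 29 lists with at least 4 measured members were tested with camera, a competitive set test, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Each list's count of genes past the threshold was made over all genes tested and also adjusted over the list alone. Camera with the correlation estimated from each list, and fry, a self-contained set test, were alternatives. With an estimated correlation, camera also takes its degrees of freedom from the few arrays instead of the genes. A call lost there is therefore not a sign of correlation between genes alone. Fry asks whether the genes of a list move on balance in 1 direction and compares them with no other genes.

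The genes named were chosen by a rule set before the data were examined: Tnc, which the series title names; the 12 largest differences in each direction among genes past the threshold whose groups did not overlap, leaving out predicted gene models; and up to 5 members of each list with the smallest p, with the members of highest mean as well for lists of other cell types, of which 3 were taken, a number not fixed beforehand. Genes outside the rule are marked as chosen after their values were seen.

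The limma and camera steps were tested on simulated data: 20 simulations of 9490 genes with the real means and spreads, in which 200 genes differed. At a log2 difference of 1 the test recovered 4.5% of the changed genes, at 2 it recovered 57.0%, at 3 it recovered 80.8%, and at 4 it recovered 90.8%. False calls made up 4.78% of all calls. In the data 1941 genes passed, and the Benjamini-Hochberg cut is less strict when more genes differ. The recovery rates from 200 changed genes may therefore be too low for the real comparison. Camera called the shifted list in 100% of simulations and 0.323% of unshifted lists, with genes simulated as independent.

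Alternatives set before the data were examined were leaving out the dimmest 25% of rows, quantile normalization of the table, centring each array on its median, the mean of a gene's rows, every row of the table, an intensity trend with a robust prior, array quality weights, an unmoderated equal-variance test, an added 2-fold threshold, and leaving out each array in turn. Counts per gene list and per family without each array, and gene families by symbol, were added after the data had been seen.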

Results

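Expression was measured in cancer stem-like cells cultured from prostates of TRAMP mice. In this transgenic strain a viral oncogene expressed in prostate epithelium drives intraepithelial neoplasia, invasive cancer and neuroendocrine tumours. The arrays cannot show whether the neuroendocrine tumours arise from the neoplasia. There were 3 samples of TPIN cells, from prostates of mice 10 to 11 weeks old with intraepithelial neoplasia, and 3 of TNE cells, from mice with neuroendocrine tumours. The age of the TNE mice is not given in the labels. Array medians were 8.99, 9.03 and 8.98 on the log2 scale in TPIN, and the lowest of all was 8.82, in TNE replicate 3. Over all rows, the correlation between arrays was 0.842 to 0.905 within TPIN, 0.825 to 0.917 within TNE and 0.549 to 0.733 between the groups. The first principal component held 62.6% of the variance and separated the 3 TPIN from the 3 TNE arrays. Values below are mean log2 expression ± SD over the 3 arrays of a group.

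The series compares the 2 kinds of cells, and its title places tenascin-C at the centre of the study. Tnc, which encodes this large glycoprotein of the extracellular matrix, was 70.2-fold lower in TNE than in TPIN. Its level was 12.69 ± 0.69 in TPIN and 6.55 ± 0.19 in TNE, a log2 difference of -6.13 (SE 0.38, limma adjusted p = 0.000274). All 3 TPIN arrays (12.02 to 13.39) lay above all 3 TNE arrays (6.33 to 6.68). Leaving out each array in turn kept the difference between -6.47 and -5.78, past the threshold each time. Tnc had the third largest difference in its direction among the genes named by the rule.

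Across the table, 1941 of 9490 genes (20.5%) passed the threshold, 976 higher in TNE and 965 higher in TPIN. The largest differences were toward TPIN: 208 genes were at least 8-fold higher in TPIN against 63 in TNE, and 77 against 8 were at least 16-fold higher. The groups did not overlap for 43.8% of genes, where chance gives 10%. The count fell to 936 without TPIN replicate 1, to 1115 without TPIN replicate 2 and to 832 without TNE replicate 2.

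Of the 12 genes with the largest differences toward TPIN, 6 encode proteins of the matrix or enzymes and inhibitors that act on it. Besides Tnc these were Lum (lumican, a collagen-binding proteoglycan), 112-fold lower, Timp1 (an inhibitor of matrix metalloproteinases), 72.4-fold, Lox (lysyl oxidase, which crosslinks collagen), 67.1-fold, Postn (periostin), 66.9-fold, and Aspn (asporin), 54.3-fold. The others were Raet1d, a ligand of the NKG2D receptor of killer lymphocytes, 56.5-fold lower, the alarmin Il33, 49.4-fold, Acpp (prostatic acid phosphatase), 48.4-fold, the secreted Wnt antagonist Frzb, 46.3-fold, the angiotensin receptor Agtr2, 40.9-fold, and Colec12, a scavenger receptor, 39.2-fold. Adjusted p lay between 0.000211 and 0.00221 in limma for these genes.

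In the other direction Cd24a, a surface glycoprotein of luminal and progenitor cells, stood apart at 80.8-fold higher in TNE (4.38 ± 0.11 in TPIN, 10.72 ± 0.90 in TNE, limma adjusted p = 0.000378). It was followed by Lrrn1 (30.5-fold), the tetraspanin Tspan13 (27.3-fold), Mboat2 (23.9-fold), Shcbp1 (20.3-fold), Cadps2, a factor of dense-core vesicle release (18-fold), and Sox11, a transcription factor of neural progenitors (17.8-fold). Prim1, the catalytic subunit of DNA primase (16.2-fold), Chd7, a chromatin remodeller (14.7-fold), Zdhhc2 (14.5-fold), Pclaf, a PCNA-binding protein (13.9-fold), and Myb, a transcription factor of progenitor cells (13.8-fold), completed the 12. Pclaf lost its call without TPIN replicate 1 and without TNE replicate 2, and the others kept theirs without any array.

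**Figure D1:**
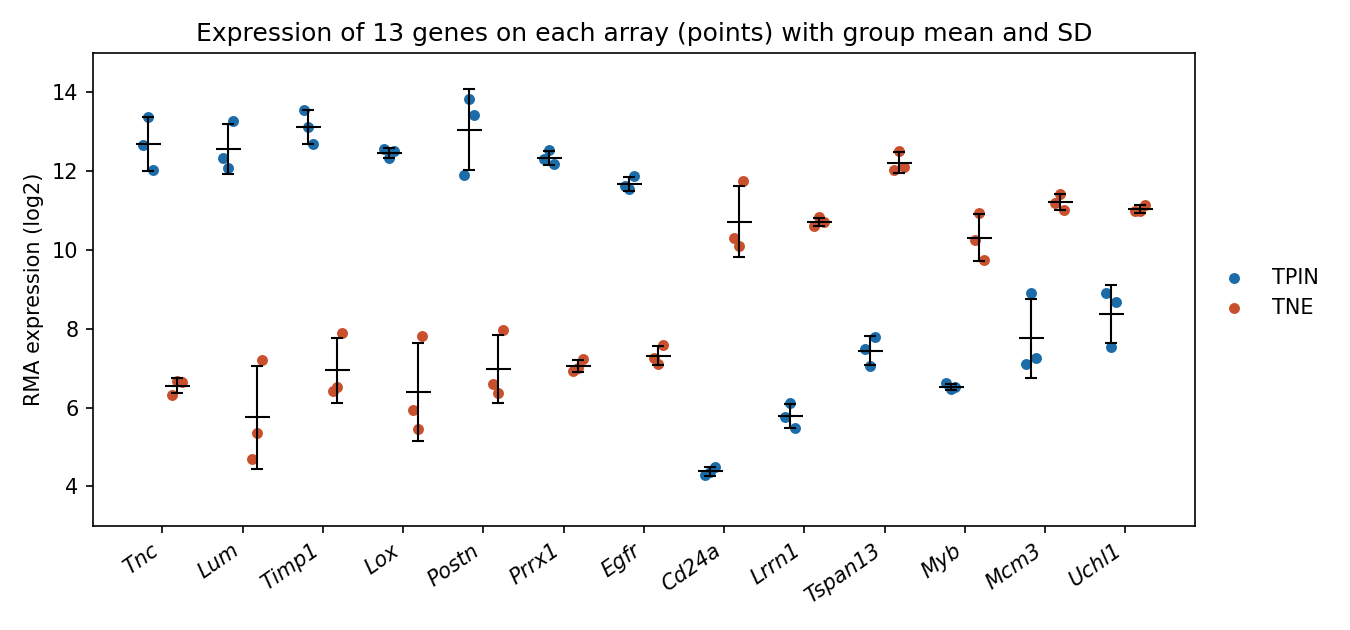
RMA expression (log2, y axis) of 13 named genes (x axis) on each array, with points for the 3 TPIN (blue) and 3 TNE (orange) arrays and black lines for the group mean and SD. Tnc lay between 12.02 and 13.39 in TPIN and between 6.33 and 6.68 in TNE, and Cd24a ran the other way, 4.38 in TPIN against 10.72 in TNE on average.

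Matrix genes were lower in TNE as a group, as was the mean of 17 fibroblast and smooth muscle markers (11.07 in TPIN, 7.68 in TNE). Of 32 measured genes of matrix glycoproteins and proteoglycans, 17 fell, 14 did not pass and 1, the laminin chain Lama5, named after its values were seen, rose. Adjusted over the list alone, 24 fell and 1 rose. Beside Tnc, the smallest p belonged to Bgn (biglycan, 12.5-fold lower in TNE), Fbln5 (8.10-fold), Thbs1 (thrombospondin, log2 difference -3.82) and Dcn (decorin, 13.72 ± 0.06 in TPIN and 10.91 ± 0.24 in TNE). Fn1, fibronectin, chosen after its values were seen, did not pass: its level was 13.72 ± 0.14 in TPIN and 11.87 ± 1.41 in TNE (limma adjusted p = 0.0719). Collagens were lower in 12 of 15 genes (13 adjusted over the list alone), led by Col6a3, Col6a2, Col5a2, Col15a1 and Col1a1, with log2 differences of -4.09, -3.46, -3.89, -3.16 and -3.93. Lama5 lost its call without any 1 of 5 of the 6 arrays. The median log2 difference was -2.43 for the glycoproteins and -2.78 for the collagens. Camera with the preset correlation gave adjusted p = 2.13e-11 and 8.16e-09, and both calls were lost with an estimated correlation (adjusted p = 0.104 and 0.125).

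Of 19 proteases and inhibitors 10 fell and none rose (13 fell adjusted over the list alone): Ctsk (cathepsin K), Mmp14, Mmp2 and Adamts5 were 16-fold, 11.1-fold, 22.7-fold and 7.13-fold lower in TNE, beside Timp1. The count was 6 without TNE replicate 2. Of 18 integrin genes, receptors that bind matrix, 7 fell, none rose and 11 did not pass, 6 of the 18 with a positive difference, and adjusted over the list alone 8 fell and 1 rose. Itga8, Itga5 (the alpha chain of the fibronectin receptor), Itgb3, Itga11 and Itgb5 had log2 differences of -3.29, -3.21, -2.34, -2.27 and -2.43. Camera gave adjusted p = 1.66e-06 for the proteases (adjusted p = 0.266 with an estimated correlation) and 0.0184 for the integrins (adjusted p = 0.432 with an estimated correlation). The integrin call was also lost without TPIN replicate 3 (camera adjusted p = 0.0828), and 1 integrin rose without TPIN replicate 3 or TNE replicate 3.

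Genes of the mesenchymal state and markers of fibroblasts were lower in TNE together with the matrix genes. Of 23 genes tied to epithelial-mesenchymal transition 16 fell and none rose (17 adjusted over the list alone), with Prrx1 (a mesenchymal transcription factor, 38.9-fold lower), Pdgfrb (21.2-fold), Inhba (38.6-fold), Lox and Tagln (15.1-fold) in front. Of 17 markers of fibroblasts and smooth muscle 12 fell, 5 did not pass and all 17 had a negative difference (13 fell adjusted over the list alone). The mean of this marker list was 11.07 ± 0.03 in TPIN and 7.68 ± 0.56 in TNE, and of its members Col3a1 had 12.51 ± 0.94 in TPIN and 9.73 ± 0.47 in TNE, and Pdgfra 12.61 ± 0.56 and 9.24 ± 1.82. Pdgfra lost its call without any 1 of the TPIN arrays. The marker list shares 6 genes with the mesenchymal list and 3 each with the glycoproteins and collagens. Camera gave adjusted p = 5.93e-10 for the mesenchymal genes and 7.85e-10 for the fibroblast markers, and with an estimated correlation these calls were lost (adjusted p = 0.104 and 0.125).

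**Figure D2:**
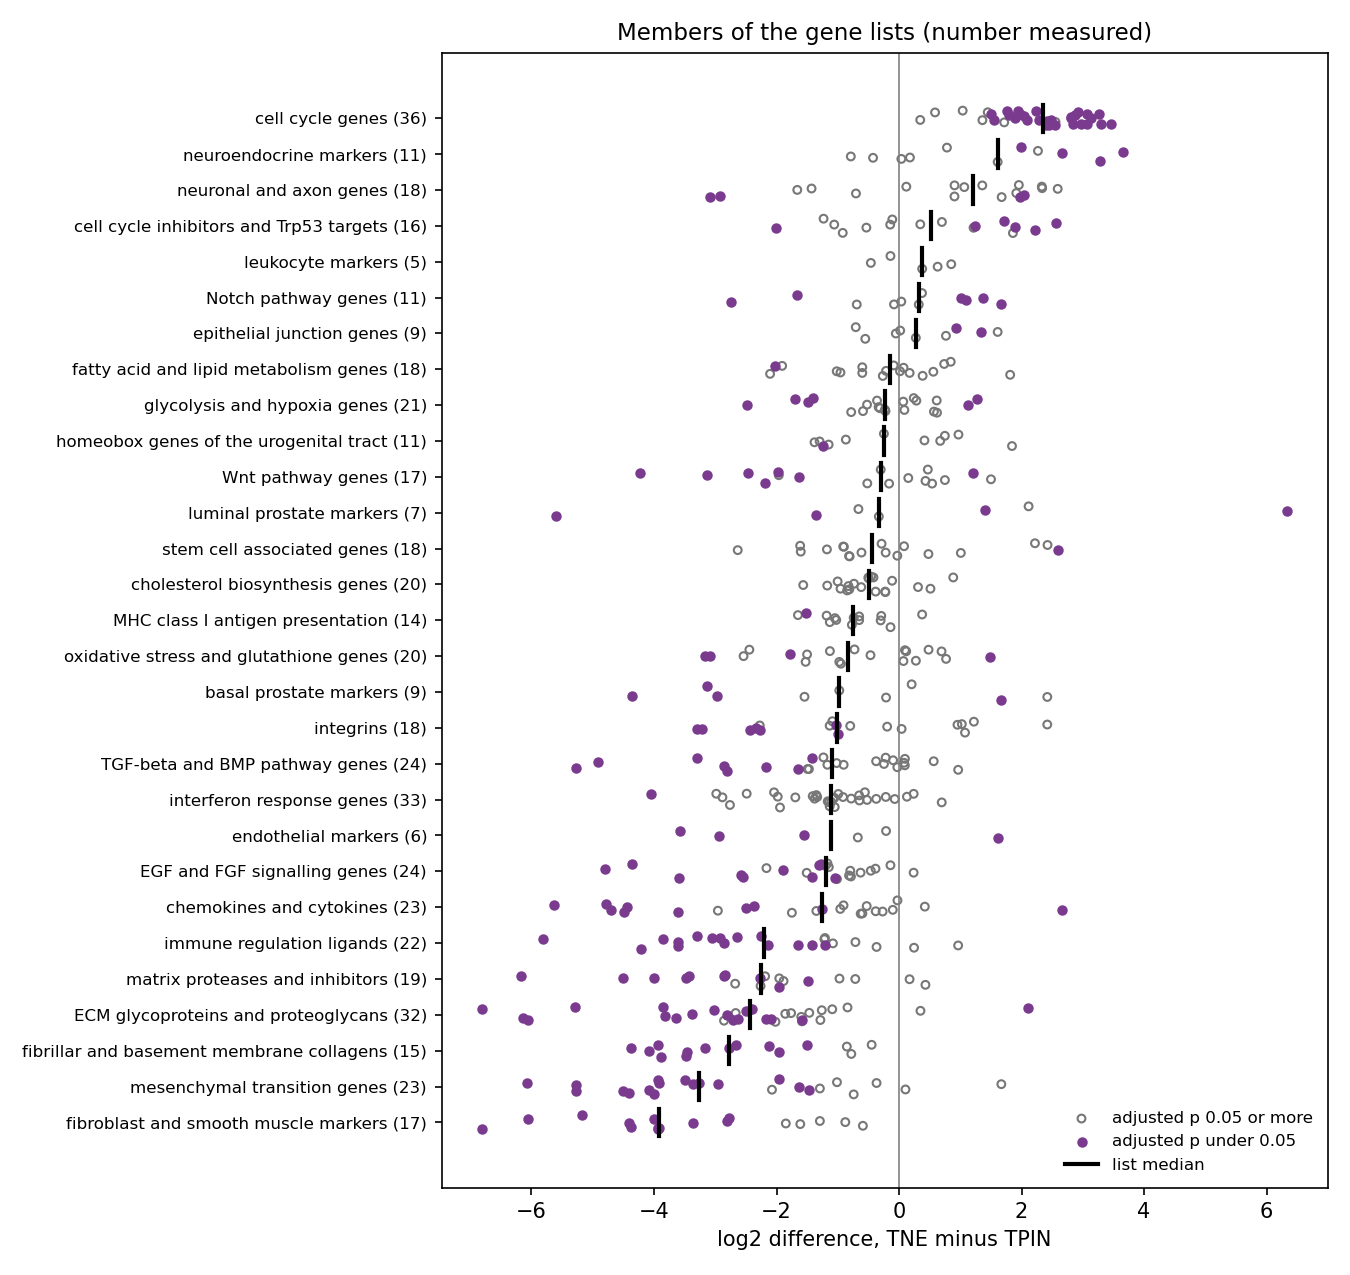
Log2 difference, TNE minus TPIN (x axis), of each measured member of the 29 tested gene lists (y axis, number measured in brackets). Filled points passed the limma threshold, open points did not, and the black bar is the list median, which ran from -3.92 for fibroblast and smooth muscle markers to 2.34 for cell cycle genes.

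Of 22 ligands and mediators of immune regulation 15 fell in TNE and none rose (17 fell adjusted over the list alone), on arrays whose fibroblast marker mean was 11.07 in TPIN and 7.68 in TNE. Raet1d and H60b, both NKG2D ligands, were 56.5-fold and 9.85-fold lower. The adhesion ligand Icam1 was 7.58-fold lower, the death receptor Fas 4.78-fold, and Ptges, a prostaglandin E synthase, 12.2-fold. Cd274, which encodes PD-L1 and was chosen after its values were seen, had 8.24 ± 0.64 in TPIN and 8.48 ± 0.13 in TNE (limma adjusted p = 0.633). The count was 8 without TPIN replicate 1, 9 without TPIN replicate 2 and 7 without TNE replicate 2. Of 23 chemokines, cytokines and their receptors 9 fell and 1 rose (11 and 1 adjusted over the list alone): Il33, Ccl2 (27.7-fold), Ccl7 (22.4-fold) and Cxcl5 (25.9-fold) were lower in TNE, and the chemokine receptor Cxcr4 was 6.32-fold higher. Camera gave adjusted p = 3.80e-08 for the immune ligands (adjusted p = 0.125 with an estimated correlation) and 0.000648 for the chemokines (adjusted p = 0.287 with an estimated correlation).

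Few genes of antigen presentation and of the interferon response passed. Of 14 genes of the class I pathway 1 fell, H2-M3 (log2 difference -1.51), and B2m had 13.41 ± 0.30 in TPIN and 12.39 ± 0.78 in TNE (limma adjusted p = 0.115). H2-M3 lost its call without TNE replicate 2, and the list's count was 2 without TPIN replicate 3 and 3 without TNE replicate 1. Of 33 interferon response genes 1 fell, Trim30a (log2 difference -4.05), a count that was 2 without TPIN replicate 1 and 5 without TNE replicate 1. Adjusted over the list alone the count was again 1 in each list. The mean of the interferon list was 8.38, 10.85 and 9.46 on TPIN arrays 1 to 3 and 9.64, 7.90 and 7.45 on TNE arrays 1 to 3, so the groups overlapped. Ifit3, an interferon-induced gene, had 10.62 ± 1.72 in TPIN and 7.64 ± 1.76 in TNE and did not pass. Camera called both lists lower in TNE (adjusted p = 0.0405 for class I and 0.00738 for interferon), and both calls were lost with an estimated correlation (adjusted p = 0.635 and 0.733). Both were also lost with fry (adjusted p = 0.230 and 0.426). Without TPIN replicate 2, TPIN replicate 3 or TNE replicate 3, camera gave adjusted p = 0.0951, 0.229 and 0.0972 for class I and 0.155, 0.0572 and 0.0882 for interferon, and for class I the call was lost without TNE replicate 2 as well (adjusted p = 0.133). The class I call was also lost with dim rows left out (camera adjusted p = 0.0825) and with the arrays quantile-normalized again (0.0536).

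Cell cycle genes were higher in TNE, on arrays whose fibroblast marker mean was 11.07 in TPIN and 7.68 in TNE. Of 36 measured genes 27 rose, 9 did not pass and none fell, and all 36 differences were positive (31 rose adjusted over the list alone). The smallest p belonged to genes of DNA replication: Cdc6, Pcna, Mcm3, Mcm2 and Uhrf1 were 4.86-fold, 4.11-fold, 11.0-fold, 7.13-fold and 7.02-fold higher in TNE. Mki67, the proliferation marker, chosen after its values were seen, was 7.80-fold higher (8.98 ± 1.56 in TPIN, 11.94 ± 0.43 in TNE) and lost its call without TPIN replicate 1, TNE replicate 2 or TNE replicate 3. The list mean was 8.33, 9.80 and 7.96 on the TPIN arrays and 10.76, 11.09 and 10.98 on the TNE arrays. Camera gave adjusted p = 2.99e-13 with the preset correlation. The correlation estimated from these 36 genes was 0.773, and the call was then lost (adjusted p = 0.443). The count was 15 without TPIN replicate 1 and 14 without TNE replicate 2. Among 16 cell cycle inhibitors and Trp53 targets 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.286). The inhibitors Cdkn2d and Cdkn2a were 3.71-fold and 5.91-fold higher in TNE, and Phlda3, which lost its call without TPIN replicate 1 or 2, was lower (log2 difference -2.02). Without TPIN replicate 1, TPIN replicate 2 or TNE replicate 2, the number that rose was 2, 3 and 2. The number that fell was 0 without TPIN replicate 1 or 2, 2 without TPIN replicate 3 and 3 without TNE replicate 1.

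Some growth factor genes and receptors fell in TNE, in cultures that all received EGF and FGF2, and the fibroblast marker mean was 11.07 in TPIN and 7.68 in TNE. Of 24 genes of EGF and FGF signalling 10 fell, none rose and 14 did not pass (11 fell adjusted over the list alone). The EGF receptor Egfr fell from 11.68 ± 0.17 in TPIN to 7.32 ± 0.25 in TNE, its ligand Ereg (epiregulin) was 27.8-fold lower and Fgf2 12-fold lower. The count was 5 without TPIN replicate 1, 3 without TNE replicate 2 and 5 without TNE replicate 3. Of 24 genes of TGF-beta and BMP signalling 8 fell, none rose and 16 did not pass (11 fell adjusted over the list alone), with Inhba, Grem1 (a BMP antagonist, 30.1-fold lower), Ltbp2 (9.83-fold) and Tgfbr3 (7.24-fold) in front. That count was 5 without TPIN replicate 1, without TPIN replicate 2, without TNE replicate 2 or without TNE replicate 3. Camera gave adjusted p = 1.66e-06 for EGF and FGF genes (adjusted p = 0.346 with an estimated correlation) and 0.00121 for TGF-beta and BMP genes (adjusted p = 0.482 with an estimated correlation). Of 17 Wnt pathway genes 6 fell and 1 rose (7 and 2 adjusted over the list alone, camera adjusted p = 0.162). The receptors Fzd2 and Fzd7 had log2 differences of -2.47 and -1.97. Dkk3, Tcf7l2 and Sfrp1, which are not receptors, were at -3.13, -1.63 and -4.23. Sfrp1 lost its call without TPIN replicate 1, TPIN replicate 3 or TNE replicate 2. The Wnt list passed with dim rows left out (camera adjusted p = 0.000608) and with fry (0.0308). Of 11 Notch pathway genes 4 rose, led by the ligand Jag2 (3.16-fold higher), and 2 fell, led by the coactivator Maml2 (6.66-fold lower), the same counts as adjusted over the list alone (camera adjusted p = 0.518). The Notch count of rises was 1 without TPIN replicate 2 or TNE replicate 2 and 2 without TPIN replicate 1 or TNE replicate 1. The Notch count of falls was 1 without any 1 array other than TNE replicate 1, and the Wnt count of rises was 2 without TNE replicate 3 and 0 without TPIN replicate 1, TPIN replicate 2, TNE replicate 1 or TNE replicate 2.

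Markers of neuroendocrine cells were measured for 11 of 32 genes, and 4 of these rose in TNE and none fell (4 adjusted over the list alone), on arrays whose fibroblast marker mean was 11.07 in TPIN and 7.68 in TNE. The list mean was 7.90, 7.54 and 7.34 on TPIN arrays 1 to 3 and 8.09, 8.99 and 9.85 on TNE arrays 1 to 3. Uchl1, a neuronal ubiquitin hydrolase, was 6.35-fold higher, at 8.37 ± 0.74 in TPIN and 11.04 ± 0.09 in TNE (limma adjusted p = 0.00464). Syt1 and Snap25, parts of the synaptic vesicle fusion machinery, had 10.45 ± 1.72 and 9.28 ± 0.80 in TNE against 7.18 ± 0.07 and 7.29 ± 0.65 in TPIN, and Elavl4, a neuronal RNA-binding protein, had 9.34 ± 2.05 against 5.68 ± 0.12. Syt1 and Elavl4 lost their calls without any 1 of the TPIN arrays, and Snap25 without TPIN replicate 2, TNE replicate 2 or TNE replicate 3. Uchl1 kept its call. Eno2 and Ncam1, chosen after their values were seen, did not pass, with log2 differences of -0.79 and 0.04. The count was 2 without TPIN replicate 1, 1 without TPIN replicate 2 and 2 without TPIN replicate 3. The list did not pass (camera adjusted p = 0.0554, fry adjusted p = 0.0936), but it did without TPIN replicate 1 (camera adjusted p = 0.0184) and without TNE replicate 1 (0.00335). Of 18 neuronal and axon genes 2 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.184): the ephrin receptor Epha3 and the guidance cue Slit2 were 8.51-fold and 7.55-fold lower in TNE, and Cntn1 and Nrcam were higher by 1.97 and 2.04 on the log2 scale, calls that 5 and 4 of the 6 arrays respectively each ended when left out. The list passed with fry (adjusted p = 0.0308). Without TPIN replicate 1 or 2 none rose, without TPIN replicate 3 the count was 1, and without TNE replicate 1 or 2 it was 3.

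Epithelial genes gave no common direction. Of 7 measured luminal prostate markers Cd24a and Fkbp5 rose and Acpp and Gata2 fell (3 and 3 adjusted over the list alone), the median log2 difference was -0.33, the mean 0.27 and camera adjusted p = 0.771, so the median and mean differ in sign, and fry called the list lower in TNE (adjusted p = 0.0308). Fkbp5 lost its call without TPIN replicate 1, TNE replicate 2 or TNE replicate 3. The luminal keratins Krt8 and Krt18, chosen after their values were seen, had 7.92 ± 0.06 and 8.27 ± 0.14 in TPIN and 7.59 ± 0.26 and 7.60 ± 0.15 in TNE, and neither passed (limma adjusted p = 0.378 and 0.0967). Of 21 basal markers in the list 9 were measured, and Krt5, Krt14 and Trp63 were not. Of the 9 measured Jag2 rose and Egfr, Dkk3 and Pdpn fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.194). The fibroblast marker mean of these arrays was 11.07 in TPIN and 7.68 in TNE. The basal list passed with dim rows left out (camera adjusted p = 0.0288) and with fry (0.0272). Without TPIN replicate 3 the number of basal markers that rose was 2. Of 9 epithelial junction genes Spint2 and F11r rose (2 adjusted over the list alone, camera adjusted p = 0.359), by 1.34 and 0.94 on the log2 scale, and both lost their calls without any 1 array except TPIN replicate 3. Without TNE replicate 3 another member, Dsc2, passed (limma adjusted p = 0.0208, and 0.107 with all arrays). Of 18 genes associated with stem cells 1 rose, Kit (6.02-fold, 1 adjusted over the list alone), a receptor of progenitor cells, which lost its call without TPIN replicate 1, TPIN replicate 2 or TNE replicate 2. Sox2 had 6.19 ± 0.19 in TPIN and 8.62 ± 1.84 in TNE (limma adjusted p = 0.0667), and camera gave adjusted p = 0.720 for the list. Without TPIN replicate 3, without TNE replicate 1 and without TNE replicate 3 the stem cell list had 1, 3 and 2 rises and 1, 3 and 0 falls.

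Markers of other cell types than fibroblasts were measured for few genes. None of 5 leukocyte markers passed over all genes or adjusted over the list alone, and Cd68 had 7.85 ± 0.29 in TPIN and 8.48 ± 0.92 in TNE (camera adjusted p = 0.627). The mean of these 5 markers was 7.36, 6.81 and 6.58 on the TPIN arrays and 7.13, 6.32 and 8.05 on the TNE arrays. Lyz2, a lysozyme of myeloid cells, had 9.39 on TNE array 3, where its TNE group was 7.13 ± 1.96. H2-Ab1, a class II chain, had 8.11 there against 6.64 ± 1.28, and 7.77 on TPIN array 1. Cd14 ran the other way, with 9.52 on TNE array 1 and 7.20 on TNE array 3. Of 6 endothelial genes Eng, Cd34 and Flt1 fell and Cdh5 rose (3 and 1 adjusted over the list alone, camera adjusted p = 0.178). The fibroblast marker mean of these arrays was 11.07 in TPIN and 7.68 in TNE. Whether the RNA of Eng, Cd34 and Flt1 came from endothelial cells was not tested. Eng was 11.9-fold lower and Cdh5 3.08-fold higher in TNE. Cd34 lost its call without TPIN replicate 2, TPIN replicate 3, TNE replicate 2 or TNE replicate 3, and Flt1 without any 1 array except TNE replicate 3. None of the 3 glial and 2 seminal vesicle or urothelial markers with a row passed, over all genes or adjusted over the list alone, and these lists and the Y-linked one had too few members for the set test. The Y-linked genes Kdm5d, Uty and Eif2s3y, measured as a check on samples that all come from males, were lower in TNE, with log2 differences of -2.12, -2.43 and -2.92 (limma adjusted p = 0.0362, 0.0387 and 0.0428), and all 3 passed adjusted over the list alone. Their mean was 9.07, 9.22 and 9.50 on the TPIN arrays and 5.22, 6.86 and 8.24 on TNE arrays 1 to 3. All 3 calls were lost without any 1 of the TPIN arrays or without TNE replicate 2, and that of Uty also without TNE replicate 1.

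Metabolic lists did not pass. Of 21 glycolysis and hypoxia genes 2 rose and 4 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.543), of which P4ha1, a prolyl hydroxylase of collagen synthesis, was 2.79-fold lower in TNE and kept its call without any array. The number that fell was 1 without TPIN replicate 2, TPIN replicate 3, TNE replicate 2 or TNE replicate 3 and 2 without TPIN replicate 1. The number that rose was 0 without TPIN replicate 1, TPIN replicate 2, TNE replicate 2 or TNE replicate 3 and 1 without TNE replicate 1. None of 20 cholesterol synthesis genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.115), although that list passed without TNE replicate 1 (0.00416), where 3 of its genes fell, and without TPIN replicate 3 1 gene rose and 1 fell. Of 18 lipid metabolism genes 1 fell, the desaturase Scd1 (log2 difference -2.03, camera adjusted p = 0.549), which lost its call without TPIN replicate 1, TPIN replicate 2 or TNE replicate 2. In that list 2 genes fell without TNE replicate 1, and 1 rose without TPIN replicate 2 or TPIN replicate 3. Of 20 oxidative stress and glutathione genes 3 fell and 1 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.162, and 0.0266 without TNE replicate 1). Gstm2 and the quinone reductase Nqo1 were 8.95-fold and 8.47-fold lower in TNE. Without TPIN replicate 3 or TNE replicate 1 the number that fell was 5. The number that rose was 2 without TPIN replicate 3 and 0 without TPIN replicate 1, TPIN replicate 2, TNE replicate 1 or TNE replicate 2. Of 11 homeobox genes of the urogenital tract 1 fell, Hoxc10 (log2 difference -1.24, camera adjusted p = 0.502), which lost its call without any 1 array except TPIN replicate 3, where 1 other gene rose. Counts adjusted over the list alone were also 1 for lipid metabolism and homeobox genes.

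**Figure D3:**
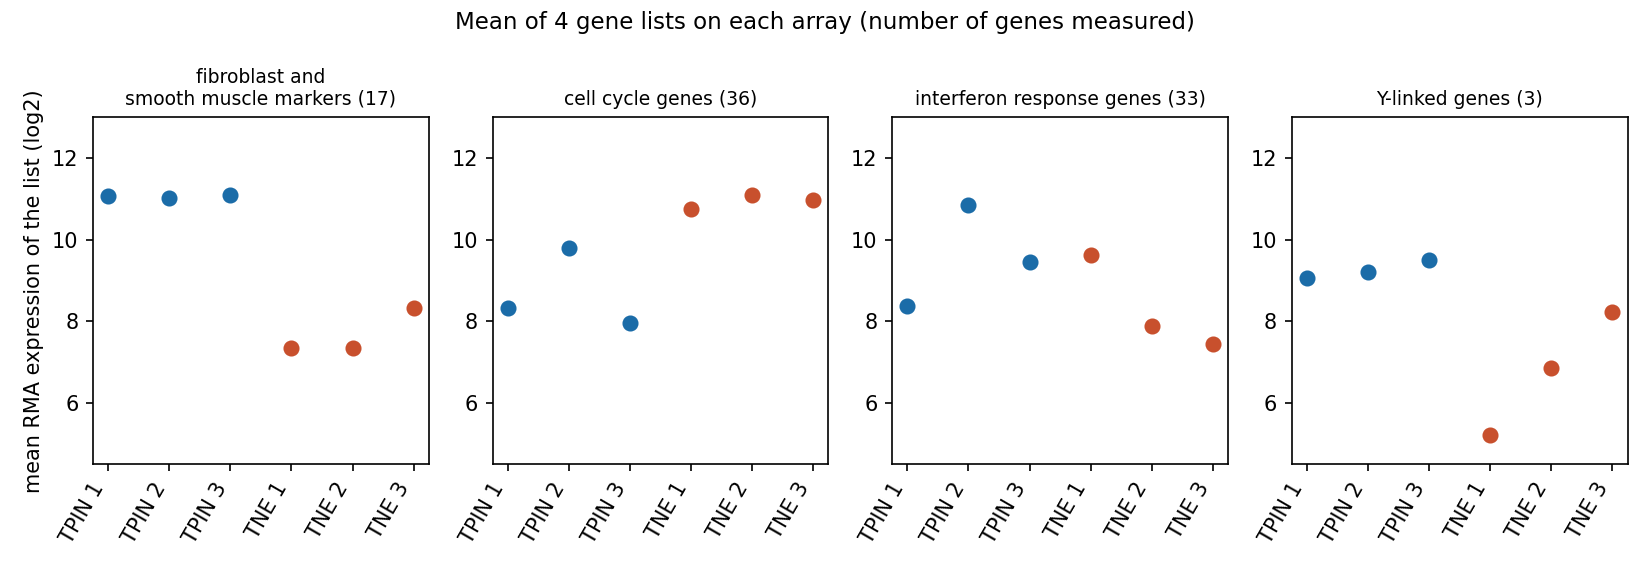
Mean RMA expression (log2, y axis) of 4 gene lists on each of the 6 arrays (x axis, TPIN blue, TNE orange, 1 point per array). Fibroblast markers and cell cycle genes separated the groups, interferon genes overlapped between them, and the 3 Y-linked genes ran from 5.22 to 8.24 on the TNE arrays against 9.07 to 9.50 on the TPIN arrays.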

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

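Rows outside the gene test carried differences too. Of 865 rows with no gene symbol or several, 136 passed the threshold when every row of the table was tested with limma, 76 higher in TNE and 60 higher in TPIN. Of these rows 90 had no symbol and cannot be named. The other 46 had several symbols and are not named here, since none can be tied to a single gene. They were set apart because they lie outside the report's comparison, and no explanation was tested.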

How the results depend on the processing

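The count of 1941 genes (976 higher in TNE, 965 higher in TPIN) moved most with array weights and without moderation. Array quality weights gave 4267 genes (2246 and 2021), and an unmoderated equal-variance test gave 706 (352 and 354). The weights were highest on TNE replicate 2 (3.264) and TPIN replicate 2 (1.742). They were lowest on TPIN replicate 3 (0.345) and TNE replicate 3 (0.492). Leaving out 1 array gave 832 to 2596 genes, 357 to 1311 higher in TNE and 475 to 1285 higher in TPIN; the lowest was without TNE replicate 2 and the highest without TPIN replicate 3, and without TPIN replicates 1 and 2 the counts were 936 and 1115. These fits test fewer samples, and the cause of the other shifts was not tested. The other 7 settings gave 1714 to 2096 genes, the most with quantile normalization, which called 1160 higher in TNE and 936 higher in TPIN (55.3% in TNE) and gave a median difference of 0.07, and no scaling moved the median difference of all genes (-0.02) by over 0.1. Tnc kept its direction and its call in the 13 alternatives run for it, from -6.47 to -5.78. Of 29 gene lists 13 passed with the preset correlation, 15 with fry and 0 with the correlation estimated for each list (camera, 5 lists at an unadjusted p under 0.05). That last setting ended every call, but it also lowers the degrees of freedom of camera. The lost calls can therefore not be put down to correlation between genes alone. The mesenchymal list, for example, lost its call at an estimated correlation of 0.035. The other settings gave 10 to 16 lists. Of 119 named genes past the threshold, 62 stayed past it in every setting run, and none of the called genes reversed. Signal over background is unknown, which limits statements about low values. No paired analysis was possible because the labels give the groups no shared replicate numbers.

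The 6 arrays can be split into 3 and 3 in 10 ways, and 1 split, the real one, gave as many genes as the 1941 of limma; the highest of the others gave 0 (449 genes at an unadjusted p under 0.05, against 3690 in the real split). With 10 splits the share cannot fall under 0.05. Each other split also mixes TPIN and TNE arrays within a group, which widens the spread there. Their counts are therefore no measure of chance, and this test decides nothing.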

Other observations

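The tests in this part, the counts of families without an array and the genes named beside the families were chosen after their values had been seen, except the split of the arrays given above. Families of genes were picked by their symbols, 21 in all, and each was compared with all other genes tested by Fisher's exact test (42 tests, Benjamini-Hochberg adjusted; genes are not independent, so these p-values are too small). The fibroblast marker mean of the arrays compared was 11.07 in TPIN and 7.68 in TNE. Centromere proteins rose in TNE in 13 of 20 measured genes and fell in none (adjusted p = 2.18e-07), and Cenpf, a kinetochore protein, was 9.17-fold higher. Kinesins rose in 13 of 25 and fell in 1 (adjusted p = 4.47e-06), with Kif2c 9.64-fold higher. Histones rose in 12 of 31 and fell in 1 (adjusted p = 0.000404), and the linker histone H1f1 was 10.3-fold higher. DNA polymerase and primase subunits rose in 7 of 17 (adjusted p = 0.00962), nucleoporins in 7 of 20 (adjusted p = 0.0216, Nup107 3.53-fold higher) and splicing factors in 9 of 31 (adjusted p = 0.0216, Srsf1 3.61-fold higher), and no member of these 3 families fell. Without TPIN replicate 1, the numbers that rose were 8 centromere proteins, 5 kinesins, 4 histones, 3 polymerase and primase subunits, 3 nucleoporins and 1 splicing factor, and without TNE replicate 2 they were 8, 5, 3, 4, 3 and 1. Histones that rose numbered 6 without TPIN replicate 3 or TNE replicate 3, and nucleoporins 4 without TNE replicate 1. Splicing factors that rose numbered 1 without TPIN replicate 2, 2 without TNE replicate 3 and 20 without TPIN replicate 3, so that count rests on single arrays. Falls in these 6 families numbered at most 3 in each without any 1 array. None of 38 ribosomal protein genes passed in limma in either direction, though 9 rose and 8 fell without TPIN replicate 3. Of genes in the other direction, 4 chosen after their values were seen were Hgf (30.6-fold lower in TNE), a growth factor of mesenchyme, Aldh1a2 (27.6-fold), which makes retinoic acid, Fgf10 (19.6-fold), a mesenchymal growth factor, and Ccl8 (37.8-fold), and all kept their limma calls without any array.

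Fibroblast and matrix genes were far higher on the TPIN arrays, on which the mean of the fibroblast marker list was 11.07 ± 0.03. Single markers varied more between these arrays, with an SD of 0.06 for Dcn, 0.94 for Col3a1 and 1.02 for Postn. A minor admixture was tested first. If fibroblasts gave under 50% of the RNA of TPIN cultures that otherwise resembled TNE cultures, no gene could be more than 2-fold lower in TPIN. Limma's treat test found 95 such genes. That argues only against a minor share of fibroblast RNA on a TNE-like culture. TPIN cells that differ from TNE cells in other genes would give such genes too. A partial share of fibroblasts among TPIN cells of that kind was therefore not tested. An outgrowth of fibroblasts that makes up nearly all of each TPIN culture may still account for it. Of the 9 epithelial junction genes with a row 2 passed the threshold, Spint2 and F11r, both lower in TPIN. In all, 6 of the 9 were lower and 3 higher in TPIN. With no array of sorted fibroblasts or epithelial cells this does not decide. A mesenchymal state of the stem-like cells themselves, tied to the kind of lesion they came from, was not tested and stays open as well. The outgrowth, the partial share and the mesenchymal state cannot be told apart here.

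The 3 Y-linked genes were lower in TNE by an amount that differed between arrays. Against the TPIN mean, Uty, Kdm5d and Eif2s3y were at -3.86, -3.41 and -4.86 on TNE array 1, at -2.52, -1.97 and -2.72 on array 2 and at -0.90, -0.98 and -1.18 on array 3. Array quality or scaling is argued against, since the median of 2847 other genes with TPIN levels in the range of the Y-linked genes was 0.144 on TNE array 1 relative to the TPIN mean. A loss of Y-linked expression shared by the 3 genes may account for the pattern but was not settled: the 3 genes ordered the 3 arrays alike (exact permutation p = 0.028), yet this test was run on the genes that showed the pattern and treats them as independent, so it decides nothing. TNE array 3, where the Y-linked genes were least reduced, also had the highest TNE mean of fibroblast (8.32), leukocyte (8.05) and endothelial markers (7.97). On arrays 1 and 2 these means were 7.35 and 7.35, 7.13 and 6.32, and 7.51 and 6.89. They did not rise from array 1 to array 2 as the Y-linked genes did. The glial mean was not highest on array 3 (8.59, against 8.67 on array 1), nor was the leukocyte marker Cd14 (7.20, against 9.52 on array 1). Whether the chromosome was lost, its genes were silenced or cells of another origin were present stays open, and Xist was not analysed here.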
